A study of Arabidopsis thaliana with 24 samples.

How the data were processed

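Per the labels, RNA was extracted from roots of 7-day-old Arabidopsis thaliana seedlings of wild type and of an EXPA1 overexpression line (8-4), whose EXPA1 copy responds to dexamethasone (Dex), a synthetic steroid. The labels give 10 µg of total RNA per library, polyA selection, a directional library kit and a 50 bp sequencing kit. The 2 genotypes and 3 conditions (control, Dex for 3 h, growth on Dex for 7 d) make 6 groups of 4 libraries, 24 in total, and each library was assigned to its group from its title. The labels name no growth or library batch, and they do not say whether the control seedlings had a mock treatment or what a shared replicate number marks.

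The authors deposited whole-number gene counts, 1 file per library, which per the file headers came from featureCounts v2.0.1 on exons summed by gene with the TAIR10-31 annotation, strand setting 2 (reverse) and a minimum mapping quality of 0. Per the labels, reads were trimmed with Trimmomatic and aligned to TAIR10 with STAR, whose versions and settings are not given in the sources used here. The authors also deposited RSEM expected counts and TPM (transcript levels scaled for length and depth) for the same libraries. The RSEM version and annotation are not given in the sources used here. By featureCounts' default, reads that map to several places or overlap several genes are left out of the counts, so genes with near-identical copies are undercounted. Reads of the transgene and of the native EXPA1 gene fall on the same gene model and were counted together.

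The files held 33602 genes, of which 32835 were matched to the reference annotation by identifier. Gene counts summed to between 20.3 and 88.7 M per library, with a median of 49.2 M. Over the 36 pairs of replicates, the variance between replicates was on average 4.69 to 312 times that of sampling alone. Each of these values is a mean over genes, in which abundant and variable genes weigh most. For such genes the spread between replicates, not depth, limits the comparisons, while for rare transcripts counting error can matter. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

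Levels are given as CPM (counts scaled to a common library total), with TMM factors. Tests used edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10 and the 6 groups, which left 21803 genes; TMM scaling; and a robust quasi-likelihood fit with 1 mean per group over all 24 libraries. The 7 comparisons of a pair of groups, and the 2 interactions (the response of the line minus that of wild type, at 3 h and at 7 d), were each adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from the same test. All tests are two-sided. The p-values measure only the spread between these samples, each of which is 1 library. The fit shares this spread between the 6 groups, which can misstate it for groups that vary more or less than the others.

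The gene lists were tested with camera from limma 3.58.1, with the preset correlation of 0.01 between genes, and adjusted over the 31 lists within a comparison; camera with a correlation estimated from the data and fry were run beside it. The lists cover cell wall, hormone, stress, nutrient, clock and cell type genes, and a list of photosynthesis genes that marks green shoot tissue in a root sample. EXPA1 was left out of the expansin list in these tests. The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule takes EXPA1, all expansins called, the 6 largest rises and falls (4 in the comparisons of wild type alone and of the line with wild type) among genes that average at least 1 CPM in a group and do not overlap between replicates. It adds up to 3 members of each list called, with at most 30 genes per comparison. Genes named for 1 comparison are also given in others. Folds against a group with 0 counts are lower bounds from a floor of 3 counts over the group, and ratios to groups with 1 to 3 counts carry an exact 95% counting interval.

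The fits were tested on simulated data with the spread of these libraries and 200 altered genes. At 4 libraries per group, edgeR recovered 26 of 49 genes altered 1.5-fold, 38 of 50 altered 2-fold and 46 of 50 altered 4-fold, with 6 false among 170 calls. For the 3 h interaction it recovered 13 of 49, 32 of 50 and 46 of 50. The camera test called a set of 16 genes raised 1.5-fold and did not call an unchanged set. The simulated genes varied independently, so these results do not cover genes that vary together, as genes of a list can.

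Alternatives covered DESeq2 1.42.0 in place of edgeR, the RLE and upper-quartile scalings, other filters on low counts, RSEM expected counts, a fit of only the groups compared, a replicate block, a null of 1.5-fold (glmTreat) and the omission of each library in turn. Added after the data were seen were the photosynthesis level as a covariate, the omission of the library with the highest and the one with the lowest photosynthesis level, and a factor for replicates 1 and 2 against 3 and 4. Also added was an enrichment test of protein domains (InterPro entries of the annotation, 1-sided Fisher's exact test). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not realigned and no transcript-level analysis was made, since the files hold gene-level values. The values of 1 gene are not reported here; it stays in the counts of genes, lists and libraries.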

Results

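The series measured gene expression by RNA sequencing in roots of wild type and of a line in which the expansin gene EXPA1 can be induced with Dex. Expansins are wall proteins that loosen cell walls, and the title of the series names hormone-regulated expansins, wall mechanics and root growth. Each of the 6 groups (wild type or EXPA1 line; control, Dex 3 h or Dex 7 d) held 4 libraries, and n = 4 for every mean given here. Depth ran from 20.3 M counts in replicate 4 of the wild-type control to 88.7 M in replicate 3 of the same group. The first component of the log CPM values carried 41.9% of the variance and the second 20%. The photosynthesis genes, which mark green shoot tissue, summed to very different levels within groups: 1848 to 25290 CPM in the wild-type controls, 1623 to 7773 in wild type at 3 h and 778 to 16558 in wild type at 7 d. In the line they summed to 8581 to 15589 CPM in the controls, 1200 to 5866 at 3 h and 2927 to 8394 at 7 d.

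EXPA1 (AT1G69530, TAIR10 chromosome 1, 26141836 to 26143500, plus strand, protein-coding) was the gene to be induced. In the line it averaged 63.1 ± 8.87 CPM (SD, n = 4) in the controls, 21040 ± 471 CPM after 3 h of Dex and 5091 ± 516 CPM after 7 d. In wild type it averaged 57.6 ± 23.4, 145 ± 52.0 and 71.0 ± 17.9 CPM. In the line EXPA1 was 333-fold higher at 3 h than in the control (log2 8.38 ± 0.34 SE, adjusted p = 1.47e-13) and 80.6-fold higher at 7 d (6.33 ± 0.31, adjusted p = 4.7e-11). Wild type also rose, 2.52-fold, at 3 h (1.33 ± 0.25, adjusted p = 0.000179), while its value at 7 d was 0.30 ± 0.25 (adjusted p = 0.618). EXPA1 took 2.12% of all counts in the line at 3 h and 0.513% at 7 d. Line and wild type were not told apart in the controls (0.13 ± 0.25, adjusted p = 0.811).

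**Figure D1:**
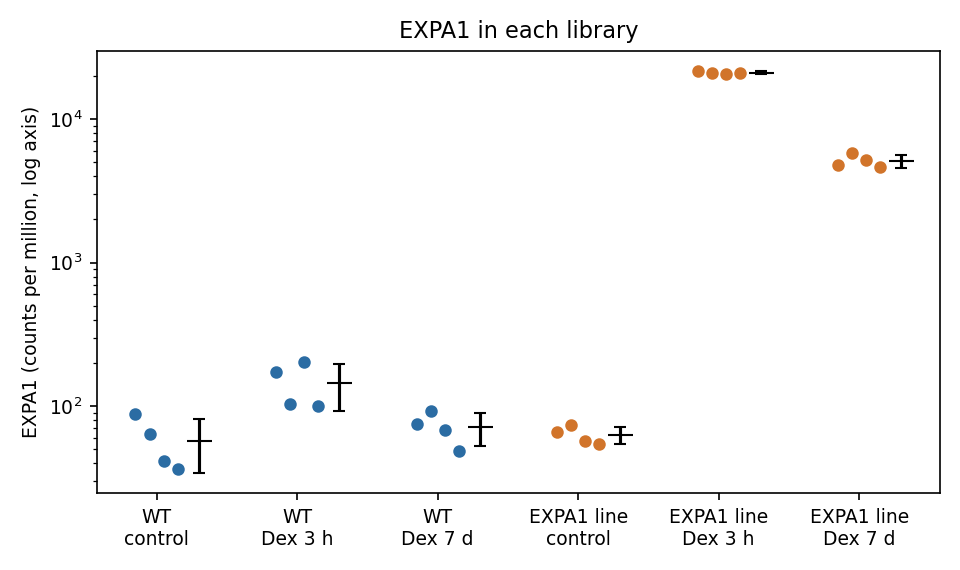
EXPA1 in CPM on a log axis, with 1 point per library and, beside the points, the group mean with its SD (n = 4). The 4 libraries of the line at 3 h lie between 20580 and 21680 CPM and those at 7 d between 4617 and 5770 CPM.

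The line at 3 h of Dex against its own control asks what follows the induction of EXPA1, together with the effect of Dex and its handling. All 16 genes of the unfolded protein response, by which cells add chaperones to the endoplasmic reticulum, rose (median log2 1.81, camera adjusted p = 1.49e-35, and adjusted p = 0.00238 with an estimated correlation; 16 adjusted over the list alone). The lumenal Hsp70 chaperone BIP3 (AT1G09080) rose most, by 9.78 ± 0.49 on the log2 scale, from a mean of 0.396 to 350 CPM (adjusted p = 4.09e-12). The co-chaperone ERDJ3A rose by 5.19 ± 0.27, and the small GTPase gene SARA1A, whose family acts in vesicle budding, by 4.96 ± 0.37. Abundant members rose less: SHD, the Hsp90 of the endoplasmic reticulum, went from 736 to 2620 CPM (1.83 ± 0.09), and HRD3A (1.18 ± 0.05) and DER1 (1.54 ± 0.08), which act in the disposal of misfolded proteins, rose as well. The smallest rise was that of the protein disulfide isomerase PDIL1-1, 0.84 ± 0.08. In wild type at 3 h, 2 of the 16 rose and 7 fell, and the list was not called (median log2 -0.24, adjusted p = 0.221). Without wild-type Dex replicate 1 or control replicate 3 10 fell (medians -0.43 and -0.39), and without control replicate 2 5 fell (-0.21). Against a null of 1.5-fold 1 rose and 1 fell.

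**Figure D2:**
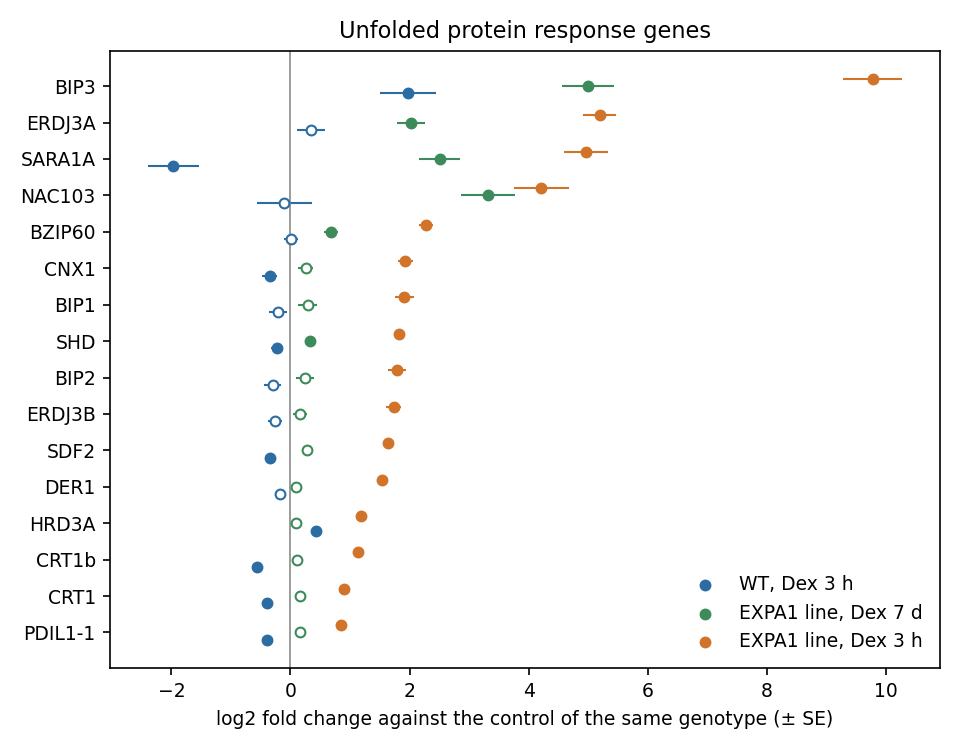
Log2 fold change (x axis, bars are SE, n = 4 per group) of the 16 unfolded protein response genes against the control of the same genotype. Filled points passed an adjusted p under 0.05; the line at 3 h lies to the right of wild type for every gene.

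Expansins other than EXPA1 mostly fell in the line at 3 h. Of 25 tested, 13 fell and 3 rose (median log2 -0.63, camera adjusted p = 0.00479, but adjusted p = 0.201 with an estimated correlation; 13 and 4 adjusted over the list alone). EXPB3 fell by 2.25 ± 0.16 on the log2 scale, from 137 to 28.8 CPM (adjusted p = 2.89e-10). EXPA4 fell by 1.55 ± 0.12, EXPA15 by 1.73 ± 0.20, EXPB1 by 1.31 ± 0.18, EXLA2 by 1.18 ± 0.28, EXPA11 by 1.05 ± 0.14 and EXPA14 by 1.03 ± 0.22. Falls under 2-fold were those of EXPA17 (-0.85 ± 0.19), EXPA20 (-0.63 ± 0.08) and EXPA13 (-0.49 ± 0.06). EXPA6 fell as well (-0.91 ± 0.28), but with the photosynthesis level as a covariate it was at -0.36 and not called (adjusted p = 0.0566). EXPA2 was the exception in size, with a rise of 6.27 ± 0.74 from 0.0881 to 7.25 CPM (adjusted p = 7.45e-07). The other 4 calls depended on single libraries. The fall of EXPA3 (-1.31 ± 0.47) was not called without control replicate 2 (-1.28) or 4 (-1.27) or Dex replicate 1 (-1.09) or 2 (-1.2). That of EXPA16 (-2.14 ± 0.76) was not called without control replicate 2 (-1.60) or Dex replicate 1 (-1.79), 2 (-1.98) or 3 (-1.98). With the photosynthesis level as a covariate EXPA3 was at -0.38 (adjusted p = 0.117) and EXPA16 at -1.11 (adjusted p = 0.113), neither called. The rise of EXPA10 (0.77 ± 0.25) was not called without Dex replicate 3 (0.63), and that of EXLA1 (0.59 ± 0.21) without control replicate 1 (0.58) or 2 (0.55) or Dex replicate 4 (0.27).

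**Figure D3:**
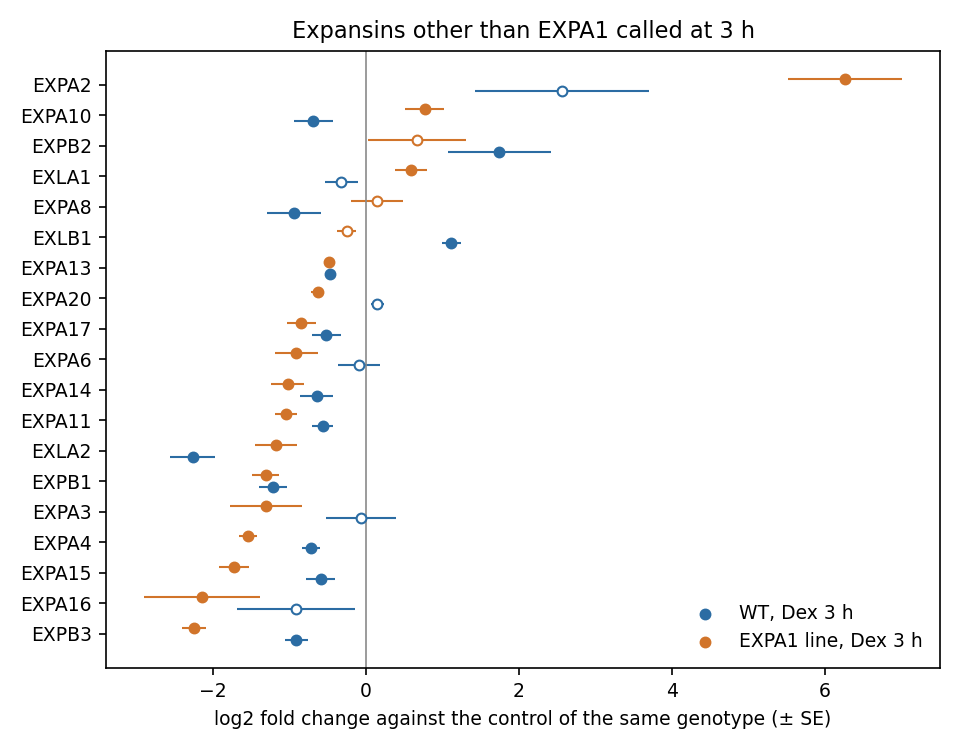
Log2 fold change at 3 h of Dex (x axis, bars are SE, n = 4 per group) of the expansins called in the line or in wild type, against the control of the same genotype. Filled points passed an adjusted p under 0.05; EXPA2 rose by 6.27 in the line, and EXPB3 fell by 2.25.

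In the line at 3 h the abscisic acid, suberin and secondary-wall lists were lower, and the ethylene response and hypoxia lists higher. All 15 abscisic acid and water deficit genes fell (median log2 -3.02, camera adjusted p = 2.5e-17; 0.00238 is the adjusted p with an estimated correlation), among them the phosphatase HAI1 (-4.93 ± 0.28) and the transcription factor HB12 (-3.12 ± 0.19). Of the 13 genes of suberin, the waxy barrier of older root walls, 12 fell and 1 rose (median -1.94, adjusted p = 1.45e-15, and adjusted p = 0.0289 with an estimated correlation), as with the exporter ABCG6 (-3.36 ± 0.19). All 14 secondary-wall and xylem genes fell (median -1.04, adjusted p = 1.44e-16, and adjusted p = 0.0377 with an estimated correlation), as with the wall glycoprotein gene FLA11 (-2.33 ± 0.08) and the laccase LAC17 (-1.47 ± 0.11). Of 11 ethylene response genes, 8 rose (median 1.43, adjusted p = 7.42e-08, and adjusted p = 0.0289 with an estimated correlation), including the receptor ETR2 (4.83 ± 0.21). Of 11 hypoxia genes, 10 rose (median 2.51, adjusted p = 1.13e-09, but adjusted p = 0.059 with an estimated correlation), including alcohol dehydrogenase ADH1 (4.75 ± 0.38). Adjusted over the list alone these counts were the same: 15, 12, 14, 8 and 10.

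Further lists were called in the line at 3 h with the preset correlation only. Monolignol synthesis, the route to lignin, was lower (9 of 14 fell, adjusted p = 1.04e-05, but adjusted p = 0.199 with an estimated correlation). So were auxin response (12 of 19 fell, adjusted p = 0.000683, but adjusted p = 0.0517 with an estimated correlation) and cytokinin response (9 of 15 fell, adjusted p = 0.00307, but adjusted p = 0.201 with an estimated correlation). Adjusted over the list alone 9, 12 and 11 fell. The photosynthesis genes were lower as a list (5 of 22 fell, none adjusted over the list alone, adjusted p = 0.0182, but adjusted p = 0.869 with an estimated correlation). Class III peroxidases, which act on wall phenolics, were higher (8 of 17 rose, adjusted p = 0.001, but adjusted p = 0.201 with an estimated correlation). So were immunity genes (8 of 15 rose, adjusted p = 0.0167, but adjusted p = 0.514 with an estimated correlation) and evening clock genes (4 of 7 rose, adjusted p = 0.0283, but adjusted p = 0.449 with an estimated correlation). The other lists were not called. Their adjusted p were 0.0644 for flavonoid synthesis, 0.121 for phosphate starvation, 0.134 for morning clock, 0.177 for nitrate response, 0.514 for touch and wounding and for phloem, and 0.604 for pectin methylesterases and for the Casparian strip. They were 0.632 for primary-wall cellulose synthesis, 0.69 for heat shock, 0.746 for root hair, jasmonate response, detoxification and iron deficiency, 0.797 for cell division, 0.872 for root tip and root cap, and 0.979 for xyloglucan endotransglucosylase/hydrolases. For this last list (7 rose, 6 fell) the median was 0.25 while the test's direction was down. For jasmonate response and detoxification (medians -0.09 and -0.23) the means were above 0, and for iron deficiency and the Casparian strip (medians -0.18 and 0.03) the test pointed away from the median.

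Among single genes of the line at 3 h, the largest rises beside EXPA1 and BIP3 included the dirigent gene DIR5 (AT1G64160, 10.43 ± 0.67 on the log2 scale, from 0.0313 to 50.2 CPM). Another was AT1G18830, a WD40 protein gene with the synonym SEC31A (8.56 ± 0.45, from 0.347 to 133 CPM). Transcripts of the homeobox gene WOX10 were at least 266-fold higher than in the control (750 against 0 counts), and those of the glycosyl hydrolase gene AT5G17500 at least 92.9-fold higher (262 against 0 counts). The largest falls were those of the thionin gene AT1G66100 (-6.06 ± 1.55), the transcription factor MYB102 (-6.00 ± 0.54) and the RING finger gene AT5G62800 (-5.94 ± 0.42). The subtilase gene AT2G39850 (-5.80 ± 1.57), the esterase gene AT2G40250 (-5.46 ± 0.57) and AT5G18600, with glutaredoxin domains (-5.33 ± 1.35), followed. The photosynthesis genes were also lower in these libraries (1200 to 5866 against 8581 to 15589 CPM). With their level as a covariate AT1G66100 was at -3.78, AT2G39850 at -3.28 and AT5G18600 at -2.74, each still called. Over all genes, edgeR called 9502 of 21803 genes, 4904 higher and 4598 lower, of which 2909 changed at least 2-fold. Within replicates 1 and 2 it called 8869 and within replicates 3 and 4 7379 genes, and 5861 in both in the same direction. Such counts, here and below, come from a single fit of all 24 libraries with a shared spread, not from separate fits. Against a null of 1.5-fold the count was 2717.

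Wild type at 3 h of Dex against its control gives the effect of Dex and its handling without the transgene, and it was as broad. All 15 abscisic acid and water deficit genes fell (median log2 -2.32, camera adjusted p = 5.85e-16, and adjusted p = 0.00414 with an estimated correlation). HAI1 fell from 43.1 to 1.32 CPM (-5.01 ± 0.29), and HB7 (-2.82 ± 0.20) and HB12 (-2.32 ± 0.18) fell too. Of 13 suberin genes, 12 fell (median -2.25, adjusted p = 1.36e-16, and adjusted p = 0.0383 with an estimated correlation). ABCG6 fell from 274 to 19.2 CPM (-3.84 ± 0.19), and so did the fatty acid hydroxylase CYP86B1 (-2.46 ± 0.13) and the fatty acyl reductase FAR5 (-2.52 ± 0.16). Of 11 ethylene response genes, 9 rose (median 1.59, adjusted p = 4.68e-08, and adjusted p = 0.0396 with an estimated correlation), such as ETR2, from 5.09 to 114 CPM (4.49 ± 0.21). Of 14 secondary-wall and xylem genes, 13 fell (median -0.73, adjusted p = 7.92e-09, but adjusted p = 0.178 with an estimated correlation), such as FLA11 (-1.30 ± 0.08), LAC17 (-1.12 ± 0.11) and the cellulose synthase CESA4 (-0.75 ± 0.08). Of 11 hypoxia genes, 10 rose (median 1.98, adjusted p = 1.18e-06, but adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone these counts were the same: 15, 12, 9, 13 and 10.

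With the preset correlation only, wild type at 3 h was called higher for class III peroxidases (7 of 17 rose, adjusted p = 0.000199, but adjusted p = 0.178 with an estimated correlation). So were phloem genes (5 of 5 rose, adjusted p = 0.0051, but adjusted p = 0.271 with an estimated correlation) and evening clock genes (5 of 7 rose, adjusted p = 0.00397, but adjusted p = 0.271 with an estimated correlation). Lower were monolignol synthesis (10 of 14 fell, adjusted p = 0.000234), cytokinin response (8 of 15 fell, adjusted p = 0.00748) and auxin response (10 of 19 fell, adjusted p = 0.0432), for each of which the adjusted p = 0.271 with an estimated correlation. Detoxification (12 of 17 fell, adjusted p = 0.0051, but adjusted p = 0.636 with an estimated correlation) and phosphate starvation genes (8 of 11 fell, adjusted p = 0.00482, but adjusted p = 0.413 with an estimated correlation) were lower as well. Of the 25 expansins, 11 fell and 2 rose, and the list was not called (median -0.47, adjusted p = 0.081). EXLA2 (-2.27 ± 0.29), EXPB1 (-1.22 ± 0.18), EXPB3 (-0.91 ± 0.15), EXPA4 (-0.72 ± 0.12), EXPA15 (-0.59 ± 0.19), EXPA11 (-0.57 ± 0.14) and EXPA13 (-0.47 ± 0.06) fell, and EXLB1 rose (1.12 ± 0.13). The other 5 calls depended on single libraries. EXPA8 (-0.95 ± 0.35) was not called without control replicate 1 (-0.64) or Dex replicate 2 (-0.78) or 4 (-0.95), and EXPA10 (-0.69 ± 0.26) without control replicate 1 (-0.57) or 2 (-0.55) or Dex replicate 2 (-0.67) or 4 (-0.68). EXPA14 (-0.65 ± 0.22) was not called without control replicate 3 (-0.51) or Dex replicate 2 (-0.55), and EXPA17 (-0.52 ± 0.19) without control replicate 3 (-0.31) or Dex replicate 2 (-0.54), 3 (-0.51) or 4 (-0.50). EXPB2 (1.74 ± 0.67) was not called without control replicate 1 (1.57), 3 (1.52) or 4 (1.47) or Dex replicate 1 (1.00) or 2 (1.77).

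The largest rises in wild type at 3 h were those of the lipase gene AT5G24180 (at least 111-fold, 337 against 0 counts) and AT5G52710, a copper transport family gene (at least 81.2-fold, 246 against 0 counts). AT1G33840 (7.46 ± 0.78 on the log2 scale) and the aquaporin NIP2;1 (7.15 ± 0.82) followed. MYB102 (-6.96 ± 0.56), the kinase gene AT5G24080 (-6.34 ± 0.47), the heat shock factor HSFA6A (-5.55 ± 0.78) and MYB121 (-5.07 ± 0.39) fell most. Across all genes, edgeR called 11205 genes, 5757 higher and 5448 lower, 2565 of them at least 2-fold. The count was 9810 within replicates 1 and 2 and 11226 within replicates 3 and 4. Against a null of 1.5-fold the count was 2493. Of the genes called higher in the line at 3 h, 3179 were also higher in wild type (1294.9 expected by chance), and of those lower 2870 were also lower (1148.9 expected), with 460 in opposite directions.

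**Figure D4:**
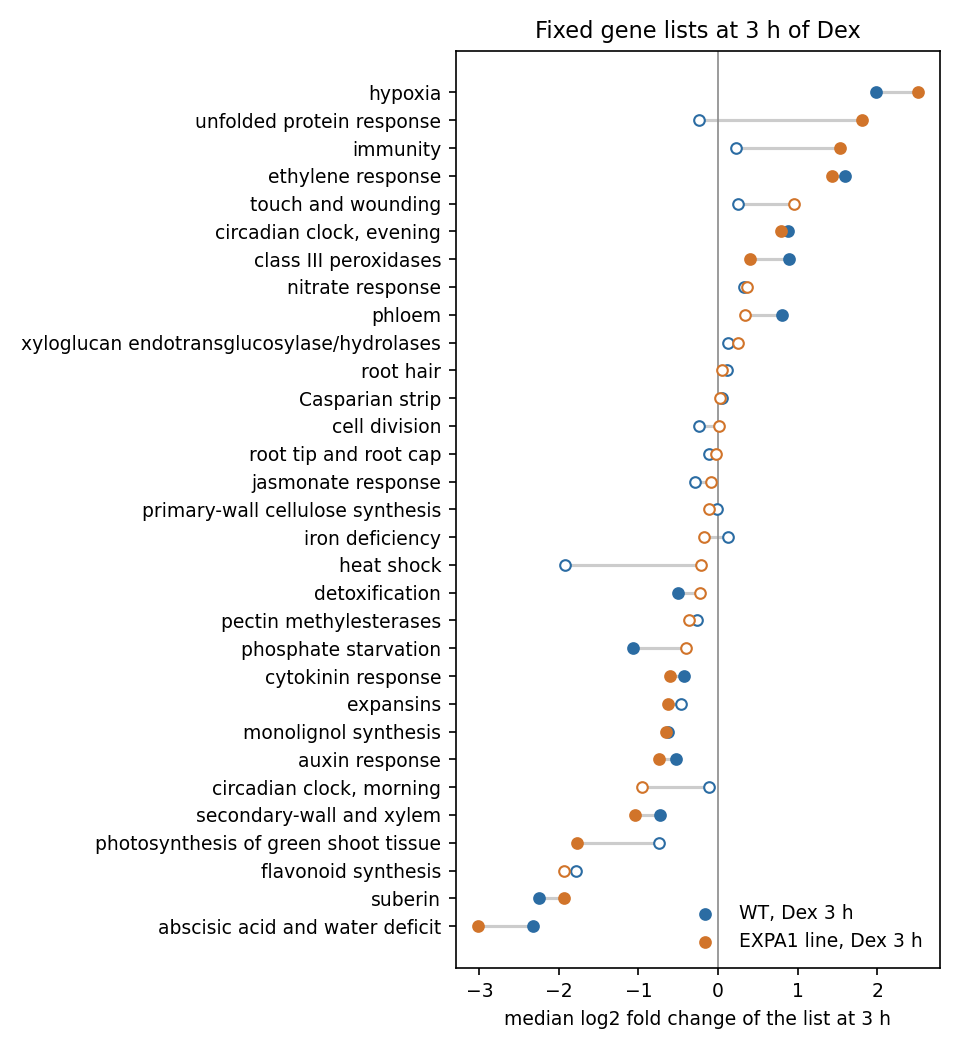
Median log2 fold change at 3 h of Dex (x axis) of the 31 fixed gene lists in the line and in wild type, each against its own control; grey lines join the 2 genotypes. Filled points passed an adjusted p under 0.05 in camera with the preset correlation; the unfolded protein response lies at 1.81 in the line and -0.24 in wild type.

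The interaction at 3 h tests whether the line responded to Dex differently from wild type. All 16 unfolded protein response genes had a higher response in the line (median log2 difference 2.07, camera adjusted p = 4.85e-83, and adjusted p = 1.64e-05 with an estimated correlation; 16 adjusted over the list alone). BIP3 differed by 7.81 ± 0.71, SARA1A by 6.92 ± 0.55, SHD by 2.06 ± 0.13, SDF2 by 1.99 ± 0.12 and DER1 by 1.71 ± 0.11. EXPA1 differed by 7.05 ± 0.39 (adjusted p = 1.02e-10), AT1G18830 by 8.16 ± 0.75 and AT4G21730, for which the annotation gives no product, by 6.99 ± 0.40. Lower in the response of the line were the galactinol synthase GolS4 (-3.57 ± 0.38), the subtilase gene AT4G21650 (-3.50 ± 0.79), AT2G28270 (-3.06 ± 0.46) and the auxin transporter PIN6 (-2.82 ± 0.68). The expansins EXPB3 (-1.34 ± 0.21), EXPA15 (-1.14 ± 0.27), EXPA4 (-0.83 ± 0.16) and EXPA20 (-0.78 ± 0.12) had a lower response in the line, as had EXLB1 (-1.37 ± 0.18), and EXPA10 a higher one (1.46 ± 0.36). Of the secondary-wall and xylem genes, 4 of 14 responded lower in the line (median -0.35, adjusted p = 0.00619, but adjusted p = 0.964 with an estimated correlation; 7 adjusted over the list alone), FLA11 by -1.04 ± 0.11. Of the detoxification genes, 4 of 17 responded higher (median 0.61, adjusted p = 0.00619, but adjusted p = 0.964 with an estimated correlation; 6 adjusted over the list alone), such as the reductase OPR1 (1.43 ± 0.27). The hypoxia genes ADH1 (1.63 ± 0.47) and HB1 (1.09 ± 0.31) responded more in the line, though the hypoxia list was not called.

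In all, the interaction at 3 h called 4027 genes, 2196 higher and 1831 lower, 593 of them at least 2-fold. Within replicates 1 and 2 it called 1735 and within replicates 3 and 4 4830 genes. The share of higher calls was 54.5%, and 66.2% with the upper-quartile scaling. Against a null of 1.5-fold the count was 232.

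The line against wild type, both at 3 h, gives the difference between plants that had the same treatment. The unfolded protein response genes were all higher in the line (16 of 16, median log2 1.88, camera adjusted p = 4.72e-100, and adjusted p = 7.22e-06 with an estimated correlation), with BIP3 at 350 against 1.79 CPM (7.63 ± 0.44). EXPA1 was 145-fold higher (7.18 ± 0.32, adjusted p = 1.62e-12) and AT1G18830 was higher by 8.06 ± 0.44. Counts of WOX10 were 330-fold those of wild type (750 against 2 counts, 95% interval 91.1 to 2730) and those of AT1G52440, an alpha/beta hydrolase gene, 268-fold (305 against 1, 95% interval 47.8 to 10600). Lower in the line were AT1G33350, a pentatricopeptide repeat gene (-4.08 ± 0.64), AT3G22142, which encodes a lipid-transfer-type protein (-3.43 ± 0.77), GolS4 (-3.31 ± 0.29) and the nucleotide-binding protein gene AT5G56220 (-2.93 ± 0.13).

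Of the expansins, 4 of 25 were higher and 6 lower in the line than in wild type at 3 h. The median was -0.18 but the mean 0.02, with the test's direction down (camera adjusted p = 0.0496, but adjusted p = 0.846 with an estimated correlation; 5 and 8 adjusted over the list alone). EXPA2 (5.62 ± 0.72), EXPA8 (1.36 ± 0.35) and EXLA1 (0.94 ± 0.21) were higher, and EXPB3 (-1.42 ± 0.15), EXPA4 (-1.29 ± 0.12), EXPA15 (-1.29 ± 0.19), EXLB1 (-1.12 ± 0.12) and EXPA20 (-0.84 ± 0.08) lower. EXLA2 (1.06 ± 0.29) was not called without replicate 4 of the line (0.64), and EXPA3 (-1.57 ± 0.47) not without wild-type replicate 3 (-1.36) or 4 (-1.48) or line replicate 1 (-1.35) or 2 (-1.42). Of 13 pectin methylesterases, enzymes that alter pectin charge, 5 were lower and 1 higher (adjusted p = 0.0262, but adjusted p = 0.0954 with an estimated correlation). PME3 stood at 347 against 677 CPM (-0.96 ± 0.08), and PMEPCRA was higher (0.38 ± 0.09). Of 14 secondary-wall genes 5 were lower (adjusted p = 0.00208), FLA11 by -1.05 ± 0.08. Of 14 monolignol genes 4 were lower (adjusted p = 0.0146), CYP98A3 by -0.81 ± 0.06 and HCT by -0.37 ± 0.05. For both lists the adjusted p = 0.918 with an estimated correlation. Adjusted over the list alone, 6, 9 and 4 members of these lists were lower. For this comparison edgeR called 3867 genes, 1925 higher and 1942 lower, 477 at least 2-fold. The share of higher calls was 49.8%, but 59% with the upper-quartile scaling and 58.6% with RSEM expected counts. It called 2192 within replicates 1 and 2 and 3398 within replicates 3 and 4. Against a null of 1.5-fold the count was 321.

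After 7 d of Dex the line differed from its own control in fewer genes than at 3 h, some of them of the unfolded protein response. BIP3 was 32-fold higher (0.396 to 12.8 CPM, adjusted p = 5.85e-07), SARA1A higher by 2.51 ± 0.34 on the log2 scale and ERDJ3A by 2.02 ± 0.24. Of the 16 unfolded protein response genes, 6 rose (7 adjusted over the list alone; median 0.27, camera adjusted p = 1.03e-14, but adjusted p = 0.104 with an estimated correlation). Against a null of 1.5-fold 4 were called, and with DESeq2 7. The median was 0.18 without Dex 7 d replicate 4. Within the line at 7 d, 3 of the 16 were lower in replicates 1 and 2 than in replicates 3 and 4 (median -0.31), a larger difference than that from the control. AT1G18830 (6.86 ± 0.43), EXPA2 (5.74 ± 0.74) and AT5G36100 (5.14 ± 0.75) rose, and WOX10 was at least 81.5-fold higher (208 against 0 counts). The uncharacterized gene AT3G46880 (-3.07 ± 0.37), AT5G62800 (-1.74 ± 0.30), the transporter gene AT2G37900 (-1.63 ± 0.34), AT4G21930 (-1.60 ± 0.33) and AT1G33340 (-1.52 ± 0.27) fell. Among the other expansins EXPA15 was lower (-0.69 ± 0.19, adjusted p = 0.0412), but it was called with all libraries or without Dex 7 d replicate 3 only. Without control replicate 1, 2, 3 or 4 its values were -0.68, -0.75, -0.66 and -0.73, and without Dex 7 d replicate 1, 2 or 4 they were -0.65, -0.62 and -0.77. Of 13 cell division genes, 8 rose, by small amounts (13 adjusted over the list alone; median 0.35, adjusted p = 2.46e-11, but adjusted p = 0.104 with an estimated correlation). They included the mitotic cyclins CYCB2;1 (0.67 ± 0.12) and CYCB2;2 (0.44 ± 0.08). Within the line at 7 d, 5 of the 13 were higher in replicates 1 and 2 than in replicates 3 and 4 (median 0.31), about as large a difference.

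The other lists called in the line at 7 d were called with the preset correlation only. Class III peroxidases (5 of 17 rose, median 0.25, adjusted p = 0.000674, but adjusted p = 0.238 with an estimated correlation), with PRX71 at 1.15 ± 0.20, were higher. Higher too were ethylene response genes (2 of 11 rose, adjusted p = 0.000615, but adjusted p = 0.191 with an estimated correlation), with ETR2 at 1.25 ± 0.19. Abscisic acid genes (3 of 15 fell, adjusted p = 0.000499, but adjusted p = 0.191 with an estimated correlation), with HB12 at -1.17 ± 0.17, were lower. Lower too were morning clock genes (3 of 6 fell, adjusted p = 0.00114, but adjusted p = 0.12 with an estimated correlation), with LHY at -1.22 ± 0.22. With at most 1 member called were hypoxia, evening clock, detoxification, immunity, jasmonate response and root hair genes (higher) and auxin response, cytokinin response, photosynthesis, flavonoid synthesis and primary-wall cellulose genes (lower), with adjusted p from 0.00385 for cytokinin response to 0.0243 for primary-wall cellulose synthesis. For these the adjusted p = 0.191 to 0.734 with an estimated correlation. Within the line at 7 d, replicates 1 and 2 were lower than replicates 3 and 4 for 12 of 17 jasmonate (median -1.30), 10 of 15 immunity (-1.25), 12 of 20 root hair (-0.59), 5 of 9 flavonoid (-1.62), 4 of 11 ethylene response (-1.27) and 3 of 11 hypoxia genes (-0.93). They were higher for 5 of 7 evening clock genes (0.48), and for 2 of 6 morning clock genes, with 1 lower (0.51). In all, edgeR called 937 genes, 607 higher and 330 lower, 178 at least 2-fold. The count was 918 within replicates 1 and 2 and 1179 within replicates 3 and 4, with 206 in both in the same direction. The share of higher calls was 64.8%, but 52.9% with RSEM expected counts, 72.6% with the upper-quartile scaling and 48.3% in a fit of only these groups. DESeq2 called 1508 genes, a fit of only these groups 2224 and a null of 1.5-fold 59. Without control replicates 1 to 4 in turn, the counts were 514, 480, 535 and 510, and without Dex 7 d replicates 1, 3 and 4 they were 570, 601 and 617. Of the 937 genes, 358 were also higher and 263 also lower at 3 h (136.5 and 69.6 expected by chance). The shared controls favour such overlap, and with the controls divided between the times 85 to 120 genes were higher at both (20.5 to 30.2 expected).

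Wild type at 7 d of Dex against its control tests growth on Dex without the transgene, and few genes were called. The lipid-transfer-type gene AT4G12500 rose from 0.179 to 1.2 CPM (2.68 ± 0.44 on the log2 scale, adjusted p = 0.009), the RING finger gene AT1G49230 rose by 1.76 ± 0.21 and the transporter gene AT3G53960 fell by 1.60 ± 0.23. Of 10 nitrate response genes, 1 rose, the repressor gene LBD38 (0.70 ± 0.09; 3 adjusted over the list alone), and the list was called (median 0.26, camera adjusted p = 0.000262, and adjusted p = 0.012 with an estimated correlation). Within the wild-type controls, 3 of the 10 were higher and 2 lower in replicates 1 and 2 than in replicates 3 and 4 (median 0.27), as large a difference. Of 15 abscisic acid genes, 2 fell (3 adjusted over the list alone; median -0.34, adjusted p = 1.27e-05, but adjusted p = 0.152 with an estimated correlation). Among them was HB12 (-0.98 ± 0.17), not called without Dex 7 d replicate 3 (-0.96) or 4 (-0.89). The other was HB7 (-0.92 ± 0.18), not called without control replicate 3 (-0.96) or 4 (-0.69) or Dex 7 d replicate 3 (-0.85) or 4 (-0.83). Evening clock genes (higher), heat shock, detoxification, Casparian strip, monolignol and secondary-wall genes (lower) were called with adjusted p from 0.000155 to 0.0473 and at most 1 member called. For these the adjusted p = 0.305 to 0.902 with an estimated correlation. Within the wild-type controls, 8 of 10 heat shock (median -1.14), 9 of 17 detoxification (-0.61), 8 of 9 Casparian strip (-0.72) and 4 of 14 secondary-wall genes (-0.21) were lower in replicates 1 and 2 than in replicates 3 and 4, and 2 of 7 evening clock genes higher (0.30). Within wild type at 7 d, 10 of 14 monolignol genes were lower (-0.47).

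The count for wild type at 7 d depended on the libraries. AT4G12500 and LBD38 were among 83 genes that edgeR called, 49 higher and 34 lower, 18 at least 2-fold (3285 at an unadjusted p under 0.05). Within replicates 1 and 2 it called 418 and within replicates 3 and 4 4163 genes. Without control replicates 1 to 4 in turn the counts were 539, 174, 45 and 36, and without Dex 7 d replicates 3 and 4 they were 24 and 20. DESeq2 called 504 genes, and with the photosynthesis level as a covariate edgeR called 186. The share of higher calls was 59% and with the upper-quartile scaling 69.9%. It was 46.4% without control replicate 1 and 75.4% without Dex 7 d replicate 1. The photosynthesis genes summed to 25290 CPM in control replicate 1 and to 778 CPM in Dex 7 d replicate 4, and without this pair edgeR called 378 genes.

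The controls of the line against those of wild type show what differed without Dex. The sterol desaturase CYP710A4 (2.47 ± 0.34 on the log2 scale), the triterpene synthase MRN1 (131 against 37.1 CPM, 1.82 ± 0.30), AT2G28270 (1.65 ± 0.35) and AT4G04223 (1.55 ± 0.29) were higher in the line. AT1G33350 was lower (-3.72 ± 0.59). Of 17 detoxification genes, 6 were lower in the line (9 adjusted over the list alone; median -0.57, camera adjusted p = 3.47e-08, but adjusted p = 0.709 with an estimated correlation). They included the glycosyltransferases UGT74E2 (-1.24 ± 0.25) and UGT73B4 (-0.88 ± 0.15). Within the wild-type controls, 9 of the 17 were lower in replicates 1 and 2 than in replicates 3 and 4 (median -0.61), about as large a difference. Of 13 cell division genes, 3 were lower (8 adjusted over the list alone; median -0.21, adjusted p = 8.71e-05, but adjusted p = 0.709 with an estimated correlation), CDC20.1 by -0.43 ± 0.09. The heat shock genes were lower (3 of 10, 6 adjusted over the list alone, adjusted p = 0.00381, but adjusted p = 0.709 with an estimated correlation). Within the wild-type controls, 8 of the 10 were lower in replicates 1 and 2 (median -1.14). Their values depended on wild-type control replicate 3. Without it HSP17.6A went from -5.14 ± 1.2 to -2.11, HSP17.4 from -3.43 ± 0.78 to -1.17 and HSP17.6II from -2.93 ± 0.89 to -0.80, none called. These were also not called without line replicate 2 (-5.03, -3.46 and -2.84) or 4 (-4.96, -3.39 and -2.68), nor HSP17.6II without line replicate 1 (-3.45) or 3 (-2.86). Iron deficiency and unfolded protein response genes (lower; adjusted p = 0.00129 and 0.00381), cytokinin response and evening clock genes (higher; 0.0186 each) and monolignol genes (lower; 0.03) were also called, but adjusted p = 0.709 to 0.712 with an estimated correlation.

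The expansin EXPA4 was lower in the line without Dex (-0.46 ± 0.12, adjusted p = 0.0195), but not called without wild-type replicate 3 (-0.38) or line replicate 1 (-0.44), 2 (-0.48) or 3 (-0.41). In all, edgeR called 1867 genes between the controls, 713 higher and 1154 lower in the line, 99 at least 2-fold and 7 against a null of 1.5-fold. The count was 541 within replicates 1 and 2 and 2912 within replicates 3 and 4, with 111 in both in the same direction. Without wild-type replicates 1, 2 and 3 the counts were 2857, 1091 and 1150, and without line replicates 1 to 4 they were 1061, 508, 1128 and 507. A fit of only these groups called 964. The photosynthesis genes summed to 1848 to 25290 CPM in the wild-type controls, and with the extreme libraries left out 3124 genes were called.

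Between line and wild type at 7 d of Dex, EXPA1 was 71.7-fold higher in the line (6.16 ± 0.31 on the log2 scale, adjusted p = 5.12e-11), AT1G18830 was higher by 6.13 ± 0.41, EXPA2 by 5.41 ± 0.72 and BIP3 by 4.33 ± 0.41. Counts of WOX10 were 225-fold those of wild type (208 against 1, 95% interval 40 to 8950). AT1G33350 (-4.10 ± 0.61) and AT5G56220 (-2.64 ± 0.12) were lower, as they were at 3 h, and so were AT5G62800 (-1.53 ± 0.30), AT5G09210 (-1.49 ± 0.29), EXPA15 (-1.12 ± 0.19) and EXPA4 (-0.68 ± 0.12). Of the unfolded protein response genes, 6 of 16 were higher (6 adjusted over the list alone; median 0.12, camera adjusted p = 1.82e-10, but adjusted p = 0.197 with an estimated correlation). A fit of only these groups called 2 of the 16 and a null of 1.5-fold 4. The median was 0.06 without line replicate 4, 0.07 without line replicate 3 or wild-type replicate 1 or 2, 0.19 without wild-type replicate 4 and 0.20 without the libraries of extreme photosynthesis level. Between replicates 1 and 2 and replicates 3 and 4 the list differed by more than 0.12, with medians of -0.31 within the line and -0.20 within wild type at 7 d. The storage proteins VSP1 (2.83-fold) and VSP2 (1.91 ± 0.35), of the 17 jasmonate response genes, were higher (adjusted p of the list 0.000275, but adjusted p = 0.472 with an estimated correlation; 3 adjusted over the list alone). Of 5 phloem genes, 3 were higher (adjusted p = 9.66e-06, but adjusted p = 0.173 with an estimated correlation), such as the filament protein gene SEOR1 (0.50 ± 0.10). Of 9 Casparian strip genes, 1 was higher (8 adjusted over the list alone; median 0.46, adjusted p = 1.19e-07, but adjusted p = 0.228 with an estimated correlation). Within the line at 7 d, 5 of the 9 were higher in replicates 1 and 2 than in replicates 3 and 4 (median 0.38), nearly as large a difference, and so were 3 of the 5 phloem genes (0.31). There, 12 of the 17 jasmonate response genes were lower in replicates 1 and 2 (-1.30).

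Also called between line and wild type at 7 d were iron deficiency, flavonoid synthesis, nitrate response, morning clock and primary-wall cellulose genes (lower) and cell division, evening clock, ethylene response, root hair and class III peroxidase genes (higher). Their adjusted p ran from 9.75e-05 to 0.0327, but adjusted p = 0.173 to 0.856 with an estimated correlation. Within wild type at 7 d, replicates 1 and 2 were lower than replicates 3 and 4 for 6 of 8 primary-wall cellulose (median -0.32), 6 of 9 flavonoid (-1.10), 7 of 19 iron deficiency (-0.56) and 12 of 20 root hair genes (-0.58). In all, edgeR called 360 genes, 271 higher and 89 lower, 104 at least 2-fold. Within replicates 1 and 2 it called 302 and within replicates 3 and 4 989 genes. DESeq2 called 745, a fit of only these groups 126, a null of 1.5-fold 52 and a fit with the photosynthesis level as a covariate 614. Without wild-type replicates 3 and 4 the counts were 172 and 207, and without line replicates 1 and 2 they were 229 and 220. Genes lower in the line numbered 210 of 463 without wild-type replicate 2 and 31 of 172 without wild-type replicate 3. The photosynthesis genes summed to 778 CPM in wild-type Dex 7 d replicate 4 and to 25290 CPM in wild-type control replicate 1; without this pair the count was 226.

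The interaction at 7 d tests whether growth on Dex changed the line differently from wild type. EXPA1 (6.03 ± 0.38 on the log2 scale, adjusted p = 7.01e-09), AT1G18830 (6.23 ± 0.72), AT5G36100 (5.97 ± 1.1), BIP3 (4.51 ± 0.70), the metal-binding protein gene HIPP27 (3.87 ± 0.48), AT4G21730 (3.64 ± 0.38) and ERDJ3A (1.95 ± 0.33) had a higher response in the line. AT3G46880 (-2.70 ± 0.50), PR-1-LIKE (-1.80 ± 0.26), the bHLH gene AT4G37850 (-1.46 ± 0.29), the peroxiredoxin gene AT1G65970 (-1.35 ± 0.24), the MADS-box gene AGL42 (-1.28 ± 0.24) and LBD38 (-0.67 ± 0.13) had a lower one. Of the unfolded protein response genes, 5 of 16 differed (10 adjusted over the list alone; median 0.35, camera adjusted p = 1.4e-14, but adjusted p = 0.0788 with an estimated correlation). With the libraries of extreme photosynthesis level left out the count was 9, and with DESeq2 or without wild-type control replicate 1 it was 7. It was 3 with the replicate block or RSEM expected counts and 2 against a null of 1.5-fold or without line control replicate 2 or 4. It was also 3 without line control replicate 1 or 3, line Dex 7 d replicate 3 or 4, wild-type control replicate 2 or 4 or wild-type Dex 7 d replicate 1. None of the 13 cell division genes was called over all genes by edgeR, while 12 were adjusted over the list alone, and the list was called (median 0.41, adjusted p = 2.8e-10, but adjusted p = 0.0788 with an estimated correlation). Of the nitrate genes 1 of 10 was lower (adjusted p = 0.00712, but adjusted p = 0.0788 with an estimated correlation). Detoxification, Casparian strip, class III peroxidase, jasmonate, root hair, hypoxia and heat shock genes (higher) and primary-wall cellulose and photosynthesis genes (lower) were called with adjusted p from 1.12e-05 to 0.045, but adjusted p = 0.528 to 0.745 with an estimated correlation. Within the wild-type controls, heat shock, Casparian strip and detoxification genes were lower in replicates 1 and 2 than in replicates 3 and 4. These were 8 of 10 (median -1.14), 8 of 9 (-0.72) and 9 of 17 (-0.61), with 0 higher. Within the line at 7 d 12 of 17 jasmonate response genes were lower in replicates 1 and 2 (-1.30). In all, edgeR called 150 genes, 98 higher and 52 lower, 69 at least 2-fold. The count was 34 within replicates 1 and 2 and 1145 within replicates 3 and 4. The share of higher calls was 65.3%, and 53.2% with RSEM expected counts. DESeq2 called 699, a fit of only these groups 244 and a null of 1.5-fold 27. Without wild-type control replicate 1 the count was 709 and without wild-type Dex 7 d replicate 3 it was 93. Without line control replicates 1, 2 and 4 it was 98, 94 and 91. With the libraries of extreme photosynthesis level left out it was 1376.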

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

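The tests of the unfolded protein response, of EXPA2 and of the WOX genes, of the pairs of groups and the groups at 7 d taken apart, of the gene lists between replicates 1 and 2 and replicates 3 and 4, and of the other splits of the samples were chosen only after the result was seen. The interaction tests were planned, and the tests of shoot tissue and of a difference common to the 3 groups were set down before their results were seen.

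The unfolded protein response, which follows the load of proteins folded in the endoplasmic reticulum, is the pattern that sets the line at 3 h apart. All 16 genes rose in the line, and their median interaction of 2.07 on the log2 scale argues against Dex and its handling in any plant, since wild type had the same treatment. The counts that EXPA1 takes shift other genes by at most 0.03, far below the smallest rise, that of PDIL1-1. With the photosynthesis level as a covariate the median interaction was 2.05, which argues against shoot tissue as the whole cause. Open are the secretion of much EXPA1 protein, which may load the endoplasmic reticulum, and the activator protein of the inducible system itself, for which the series has no line without EXPA1; neither was tested.

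Replicates 1 and 2 differed from replicates 3 and 4 within some groups: edgeR called 4539 genes in the wild-type controls, 3767 in wild type at 7 d and 2203 in the line at 7 d. It called 0 in wild type at 3 h (518 at an unadjusted p under 0.05), 0 in the line controls (154) and 3 in the line at 3 h (1946). With the photosynthesis level as a covariate, the calls summed over the first 3 groups came to 36.6% of that number (279, 1197 and 2373). Of these, 274, 1114 and 1952 had also been called without it. The median size of the called genes went from 0.73 to 0.48 in the wild-type controls and from 0.69 to 0.57 in wild type at 7 d, so shoot tissue cannot be told apart from other causes there. In the line at 7 d the count with the covariate was 108% of that without it. There 1952 of the 2203 calls were kept, which argues against shoot tissue in that group. For a difference common to all 3 groups, 75.2% of the genes called in 2 or more groups went the same way. This lies between the bounds set down for and against it and decides nothing. Of the 1331 genes shared by the wild-type controls and wild type at 7 d 61.6% went the same way. Of the 531 shared by the wild-type controls and the line at 7 d only 33.7% did. But of the 4539 calls of the wild-type controls only 274 were kept with the photosynthesis level as a covariate. A difference common to the 3 groups could lie beneath the one that goes with this level, so the shared genes do not decide against it. A difference common to both groups at 7 d alone, such as a growth or library batch, is consistent with their shared genes, of which 99.1% of 1375 went the same way (380.6 shared expected by chance); the labels name no batch.

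Root hair genes, which act in the outgrowth of epidermal cells, were among those that differed between replicates 1 and 2 and replicates 3 and 4. Of 20, 12 were lower in replicates 1 and 2 in each of the wild-type controls (median log2 -0.54), wild type at 7 d (-0.58) and the line at 7 d (-0.59). In the wild-type controls 16 of 22 photosynthesis genes were higher in replicates 1 and 2 (median 3.07), 8 of 9 Casparian strip genes lower (-0.72) and 8 of 10 heat shock genes lower (-1.14). In the line at 7 d, replicates 1 and 2 were lower for 13 of 15 touch and wounding genes (-3.43), 12 of 17 jasmonate response genes (-1.30), 10 of 15 immunity genes (-1.25) and 5 of 9 flavonoid synthesis genes (-1.62).

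EXPA2, WOX14 and WOX10 rose with EXPA1. EXPA2 is a paralog of EXPA1, and reads of EXPA1 assigned to it would keep a constant ratio. The log2 ratio of EXPA2 to EXPA1 was 1.47 higher at 7 d than at 3 h (n = 4 each). The exact permutation p = 0.0286 is the smallest that 70 reassignments allow. The SD of the ratio was 0.23 at 3 h and 0.64 at 7 d, with 0.346 and 1.01 counts of EXPA2 per 1000 of EXPA1. This change in the ratio argues against read sharing as the whole cause. WOX14 (AT1G20700), chosen after its values were seen, lies beside WOX10 on chromosome 1, which could place the construct near them. From 3 h to 7 d WOX14 fell by 1.97 ± 0.12 and EXPA1 by 2.05 ± 0.26, a difference of 0.08 ± 0.28. But 20 of 102 other raised genes (19.6%) fell alike. Against the line's controls WOX14 was 4.93 ± 0.14 higher at 3 h and 2.96 ± 0.13 higher at 7 d. Its interaction at 3 h was smaller, 2.97 ± 0.18, so by these estimates WOX14 rose at 3 h in wild type as well. The fall in the line also holds the part seen in wild type, and its match with EXPA1 does not decide. An insertion there cannot be told apart from other causes. The neighbours HMGB3 (0.03 and 0.17 in the line at 3 h and 7 d) and AT1G20720 (0.09 and 0.16) were not called against the line's controls. Both were called higher in the line than in wild type at 3 h (0.25 and 0.51) and in the interaction at 3 h (0.35 and 0.37), far below WOX14 in the same tests (3.36 and 2.97).

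The response to Dex differed between line and wild type, by the interaction test, in 4027 genes at 3 h and 150 at 7 d. At 3 h the induced gene EXPA1 differed by 7.05, AT1G18830 by 8.16, BIP3 by 7.81, AT4G21730 by 6.99 and SARA1A by 6.92; AT1G52440 differed by 8.92, but from 1 count in wild type with Dex. The unfolded protein response genes SDF2 (1.99), SHD (2.06) and DER1 (1.71) had a higher response in the line. The response was lower for GolS4 (-3.57), AT4G21650 (-3.50), AT2G28270 (-3.06) and PIN6 (-2.82). Among expansins EXPA4 (-0.83), EXPA15 (-1.14), EXPA20 (-0.78), EXPB3 (-1.34) and EXLB1 (-1.37) responded lower and EXPA10 (1.46) higher. Of the detoxification genes OPR1 (1.43), UGT73B4 (1.12) and OPR2 (0.69) responded higher, of the secondary-wall genes FLA11 (-1.04), CESA4 (-0.44) and CESA8 (-0.45) lower, and of the hypoxia genes HB1 (1.09) and ADH1 (1.63) higher.

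The following interactions at 3 h were not called when single libraries were left out. EXLA1 (0.92) was not called without wild-type control replicate 3 (0.89) or 4 (0.83), wild-type Dex 3 h replicate 2 (0.88) or 3 (0.89), line control replicates 1 to 4 (0.89, 0.92, 0.92 and 0.94) or line Dex 3 h replicate 4 (0.64). HRE2 (2.05) was not called without wild-type control replicate 3 (1.57), wild-type Dex 3 h replicate 4 (1.96), line control replicate 2 (1.98) or 4 (1.87) or line Dex 3 h replicate 3 (1.81), nor with the photosynthesis level as a covariate (1.58). AT3G22142 (-3.29) was not called without wild-type Dex 3 h replicate 1 (-2.69), line control replicate 2 (-2.84) or line Dex 3 h replicate 1 (-3.01), 2 (-3.11) or 4 (-3.31). AT5G63250 (-3.36), a gene with an X8 domain, was not called without wild-type control replicate 2 (-2.94) or 3 (-2.93), wild-type Dex 3 h replicate 2 (-3.32), 3 (-3.26) or 4 (-3.38), line control replicate 1 (-3.21), 2 (-3.33) or 4 (-3.41) or line Dex 3 h replicate 2 (-3.27) or 4 (-3.11), nor with the photosynthesis level as a covariate (-2.91).

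At 7 d the interaction was 6.03 for EXPA1, 6.23 for AT1G18830, 5.97 for AT5G36100, 4.51 for BIP3, 3.87 for HIPP27, 3.64 for AT4G21730 and 1.95 for the co-chaperone ERDJ3A. It was negative for AT3G46880 (-2.70), PR-1-LIKE (-1.80), AT4G37850 (-1.46), AT1G65970 (-1.35), AGL42 (-1.28) and the nitrate-related gene LBD38 (-0.67). SARA1A (2.44) was not called without line control replicate 2 (2.34) or 4 (2.29). AT4G02850 (-1.22) was not called without wild-type control replicate 3 (-1.09) or 4 (-1.10), wild-type Dex 7 d replicate 3 (-1.12) or 4 (-1.21), line control replicates 1 to 4 (-1.23, -1.26, -1.16 and -1.26) or line Dex 7 d replicate 1 (-1.13) or 2 (-1.19).

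Single libraries lay far from the other 3 of their group in 23 of 361 groups of values tested, where chance alone gives about 1 in 20, or 18.1. In wild-type control replicate 3 the small heat shock genes, which respond to misfolded proteins, were high. AT1G07400 was at 32.32 CPM (others 1.934 to 3.154), HSP17.4 at 38.01 (1.28 to 3.647), HSP17.6A at 37.11 (0.5453 to 1.796) and HSP17.6II at 6.009 (0.3082 to 0.4973). The same library stood out for ADH1 at 13.47 (8.73 to 9.314), GH3.5 at 39.84 (31.39 to 32.5), OPT3 at 62.22 (53.03 to 54.59) and LHY at 99.31 (122.9 to 125.1). In wild-type control replicate 4, the library of lowest depth, AT5G24080 was at 32.77 (18.99 to 20.67), CKX4 at 4.583 (8.938 to 9.122) and GH3.6 at 30.06 (35.79 to 36.19), and 22651 genes were detected (23392 to 23495).

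In the other groups fewer values stood out. In line control replicate 4 AT4G21650 was at 4.021 CPM (2.27 to 2.485) and CESA8 at 53.39 (43.42 to 44.84). In line Dex 3 h replicate 2 CYP98A3 was at 97.99 (87.86 to 88.76) and OPR2 at 65.95 (53.28 to 55), and in replicate 4 EXLA1 at 27.79 (13.7 to 15.02) and PMEPCRA at 894 (1173 to 1207). EXPA20 was at 10.69 in wild-type Dex 3 h replicate 1 (9.46 to 9.643) and GolS4 at 9.814 in replicate 2 (5.63 to 5.951). AT1G65970 was at 32.79 in wild-type Dex 7 d replicate 4 (44.79 to 45.38) and HB12 at 17.2 in line Dex 7 d replicate 1 (22.77 to 23.2).

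Other splits of the same libraries were counted for each comparison by edgeR. No other split called as many genes as the real one for the line at 3 h (9502 genes, highest other split 296), the line at 7 d (937, highest other 37) and wild type at 3 h (11205, highest other 2904). The same holds for the controls (1867, highest other 0, with 389 to 4458 genes at an unadjusted p under 0.05 in the other splits) and line against wild type at 3 h (3867, highest other 4). For these 5 comparisons 1 of 35 splits, the real one, called as many, the smallest share that 35 splits allow. No other split did so for the interaction at 3 h either (4027, highest other 1793, 1 of 100 splits). The other splits mix the groups compared, so real differences widen their spread and lower their counts. Their low counts alone therefore do not exclude chance. Chance cannot be excluded either where other splits called as many. That was so for wild type at 7 d (83, highest other 2890, 4 of 35 splits), line against wild type at 7 d (360, highest other 4534, 2 of 35) and the interaction at 7 d (150, highest other 1958, 5 of 100). These largest splits call many times the real counts and point to a structure of the samples. For wild type at 7 d and for line against wild type at 7 d they set replicates 1 and 2 of both groups against replicates 3 and 4. For line against wild type at 7 d this division was the only other split to reach the real count. Each of the remaining splits called at most 1 gene. Within replicates 1 and 2 these comparisons called 418 and 302 genes and the interaction at 7 d 34, and within replicates 3 and 4 4163, 989 and 1145. Called in both, in the same direction, were 25, 162 and 20. The line at 7 d, with 937 calls, had 206 such genes, and the controls, with 1867, had 111. The line at 3 h, with 9502, had 5861.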

How the results depend on the processing

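The tests with the photosynthesis level as a covariate, with the libraries of extreme photosynthesis level left out and with replicates 1 and 2 against 3 and 4 as a factor were chosen only after the result was seen. The other alternatives were planned. EXPA1, BIP3 and SHD are among the named genes.

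Of 4954 values of named genes under the alternatives, 4499 kept their direction and their side of the threshold, 453 kept the direction but were no longer called, and 2 reversed. Both were the uncalled EXPA1 difference between the controls (0.13): -0.02 without wild-type control replicate 4 (-0.02 to 0.41 with each library left out in turn) and -0.02 with the photosynthesis level as a covariate. All named gene values kept direction and call with DESeq2, and with the replicate block 215 of 231 did. With the replicate block the line at 3 h called 9242 genes, the line at 7 d 802, wild type at 3 h 11049 and wild type at 7 d 67, all near their counts without it.

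Against a null of 1.5-fold, which asks for larger changes, counts dropped to 2717 for the line at 3 h, 59 for the line at 7 d, and 2493 and 1 for wild type at 3 h and 7 d. They dropped to 7 for the controls, 321 and 52 for line against wild type at 3 h and 7 d, and 232 and 27 for the interactions. Fits of only the groups compared had fewer samples and took the spread from those groups alone. They called 2224 for the line at 7 d, 964 for the controls, 126 for line against wild type at 7 d and 244 for the interaction at 7 d. For wild type at 7 d such a fit called 0 by edgeR (1644 at an unadjusted p under 0.05) and 217 by DESeq2. Pairs of replicates varied 39 to 312 times as much as sampling alone in the wild-type controls, but 4.69 to 25.8 times in the line controls. The main fit shares the spread between groups. Its p-values can be too small for groups that vary more and too large for groups that vary less. DESeq2 called 1508 for the line at 7 d, 504 for wild type at 7 d, 745 for line against wild type at 7 d and 699 for the interaction at 7 d. With the photosynthesis covariate wild type at 7 d called 186 and line against wild type at 7 d 614. Without the libraries of extreme photosynthesis level wild type at 7 d called 378, the controls 3124, line against wild type at 7 d 226 and the interaction at 7 d 1376. For the fits of only the groups compared, DESeq2, the covariate and the libraries left out, the cause was not tested.

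With single libraries left out the counts ranged from 8188 to 9071 for the line at 3 h, 480 to 778 for the line at 7 d, 9935 to 11337 for wild type at 3 h, and 20 to 539 for wild type at 7 d. They ranged from 507 to 2857 for the controls, 2957 to 3932 and 172 to 463 for line against wild type at 3 h and 7 d, and 3017 to 4585 and 91 to 709 for the interactions. In the authors' TPM EXPA1 was 8.42 higher in the line at 3 h than in its controls and 7.25 higher than in wild type, against 8.38 and 7.18; the cause was not tested.

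With the correlation estimated from the data, camera called 5 lists for the line at 3 h, the unfolded protein response among them, 3 for wild type at 3 h, 1 for wild type at 7 d, 1 for line against wild type at 3 h and 1 for the interaction at 3 h. It called 0 for the line at 7 d, the controls, line against wild type at 7 d and the interaction at 7 d (6, 0, 5 and 4 at an unadjusted p under 0.05). The test allows for genes of a list that vary together, which lowers such counts by construction. The fry test called 9 for the line at 7 d, 2 for wild type at 7 d, 0 for the controls (7 at an unadjusted p under 0.05). It called 8 and 4 for line against wild type at 3 h and 7 d, and 5 and 4 for the interactions. With the replicate block the interaction at 3 h called 5 lists; the cause was not tested. Asking for 2-fold in both comparisons leaves fewer genes by construction. The line at 3 h and 7 d shared 109 higher and 22 lower, line and wild type at 3 h 870 and 806, and line and wild type at 7 d 1 and 2. The interactions, which use the same controls, shared 35 and 3, and line against wild type at 3 h and 7 d 39 and 5.

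Depth ranged from 20.3 to 88.7 M counts, and limits rare transcripts such as WOX10 in wild type, with 2 counts over the group at 3 h.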

Other observations

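The tests of protein domains below were all chosen only after the data were seen. They are a selection, since 893 domains were tested and many more were enriched than are given here. In the line at 3 h 34 were enriched among the genes called higher and 132 among those lower. In wild type at 3 h these counts were 48 and 44, in the interaction at 3 h 48 and 51, and between line and wild type at 3 h 31 and 62. Genes with the core histone domain, the proteins that package DNA, were mostly lower in wild type at 3 h of Dex, 38 of 42 (11 expected, adjusted p = 1.87e-15 by Fisher's exact test). So were 21 of 24 proteasome subunits, which degrade proteins (6.3 expected, adjusted p = 1.38e-07). Higher in wild type at 3 h were 97 of 152 genes with the NB-ARC domain of immune receptors (41.0 expected, adjusted p = 1.49e-18). In the interaction at 3 h the line responded higher for 27 of 42 core histone genes (4.5 expected, adjusted p = 1.05e-13) and 24 of 51 genes with the DEAD-box Q motif of RNA helicases (5.5 expected, adjusted p = 1.35e-08). In the controls of the line 16 of 24 proteasome subunits (1.3 expected, adjusted p = 3.72e-12) and 14 of 42 core histone genes (2.4 expected, adjusted p = 5.06e-06) were lower than in wild type. These comparisons share the wild-type controls.

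Further domains were enriched among the calls of the line. Of 10 genes with Sec23/Sec24 domains, which coat vesicles that leave the endoplasmic reticulum, 5 were higher in the line than in wild type at 3 h (0.9 expected, adjusted p = 0.0367). Of 26 aquaporins, the water channels, 13 were lower in that comparison (2.4 expected, adjusted p = 9.32e-06) and 12 in the interaction (2.3 expected, adjusted p = 0.000109). In the line at 3 h 86 of 186 cytochrome P450 genes (40.4 expected, adjusted p = 2.21e-11) and 13 of 16 laccases, which polymerize lignin (3.5 expected, adjusted p = 2.6e-05), were lower than in its controls. In wild type 12 of 16 laccases fell at 3 h as well (4.2 expected, adjusted p = 0.00305). Against wild type at 3 h 41 of 186 cytochrome P450 genes were lower in the line (17.5 expected, adjusted p = 1.09e-05). In the line at 7 d 11 of 59 kinesins (1.7 expected, adjusted p = 0.000572), 12 of 74 haem peroxidases (2.2 expected, adjusted p = 0.000572) and 6 of 18 cyclins (0.5 expected, adjusted p = 0.00129) were higher. In contrast, 5 of 41 genes with an AUX/IAA domain, which occurs in proteins of auxin signalling, were lower (0.6 expected, adjusted p = 0.0379). Fisher's test treats genes as independent, so that its p-values are too small where genes vary together.

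AT5G56220 and AT1G33350 were lower in the line in each of the 3 conditions: AT5G56220 by -2.57 in the controls, -2.93 at 3 h and -2.64 at 7 d, and AT1G33350 by -3.72, -4.08 and -4.10 on the log2 scale.

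A shared replicate number did not pair libraries: of 60 pairs of libraries with the same number in different groups the median correlation of residuals was 0.0121 (-0.484 to 0.592), and 6 of 24 libraries correlated best with their own number. Among the control and Dex 7 d groups, pairs on the same side of the division into replicates 1 and 2 and replicates 3 and 4 had a median correlation of 0.209 (37 of 48 above 0). Pairs across it had -0.203 (8 of 48). Where 1 library of the pair came from a Dex 3 h group the signs were opposite: -0.16 on the same side (21 of 64 above 0) and 0.175 across it (47 of 64). Between the Dex 3 h groups they were 0.177 (6 of 8) and -0.179 (2 of 8). Residuals were centred within each group, so values across the division roughly mirror those on the same side and add no evidence.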
